A study of Homo sapiens with 4 samples.

How the data were processed

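RNA was profiled from SUM149PT cells, a cell line established from an inflammatory breast cancer, that had been stably infected with a lentivirus. The labels name 2 groups of 2 libraries: a vector control carrying a control construct, and an EMP2 knockdown carrying a short hairpin RNA (shRNA), a transcript that the cell processes into a small RNA against EMP2 mRNA. By their labels both knockdown libraries carried the same construct; its sequence is not given in the sources used here. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

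Per the labels' protocols, 1 µg of total RNA per sample was depleted of ribosomal RNA with a Kapa kit with RiboErase and sequenced on an Illumina HiSeq as single reads of 50 bases, with the samples multiplexed. Per the submitters' processing notes, bcl2fastq 2.17, STAR, DESeq2 and the genome build GRCh38 were used; the counting program, the annotation and the strand setting are not given in the sources used here, so reads of genes that overlap on opposite strands cannot be told apart. The deposited table gives, for 25343 genes, values that its authors name as TMM-normalized CPM: reads per gene brought to a common library total, after scaling by the trimmed mean of M values, which sets the bulk of genes equal between libraries. CPM is not corrected for gene length, so levels were compared between libraries and not between genes. A shift of most mRNAs in one direction would be removed by this scaling.

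The whole reads behind the CPM values were recovered. In each library 100% of the values were whole multiples of a smallest step, to within 0.1 read, and 1 read was worth 0.0692 and 0.0757 CPM in the controls and 0.0717 and 0.0749 CPM in the knockdowns. The recovered totals were 14647053 and 13387914 reads in the controls and 13874599 and 13360907 reads in the knockdowns, so that 3 reads, taken as the limit that a count of 0 allows, came to between 0.208 and 0.227 CPM. That limit covers counting error only. Replicates were checked for duplication with a chi-square test of the recovered reads: the controls differed by 1.64 per gene over 15130 genes and the knockdowns by 1.62 per gene over 15100 genes, both above the 1 of pure counting noise, so all 4 libraries were counted.

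The main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 0.5), with an abundance trend in the empirical Bayes step, group as the single term, two-sided, and Benjamini-Hochberg adjustment over 13661 genes with at least 1 CPM in at least 2 of the 4 libraries. Genes with an adjusted p under 0.05 were called. All log2 changes are on the log2(CPM + 0.5) scale, which understates the change of low genes, and are given as knockdown minus control with the standard error (SE). Gene lists were compared with the other genes by camera in limma with a preset correlation of 0.01 between genes, two-sided, in 30 lists with at least 3 tested members, with Benjamini-Hochberg adjustment over these lists. Camera with an estimated correlation and fry were alternatives. The first estimates the correlation from 2 residual degrees of freedom. It also takes its p from a t distribution with these 2, against far more with the preset correlation. Few lists can therefore pass it, whatever their correlation. On the recovered reads edgeR 4.0.16 (quasi-likelihood test) called 2136 genes higher and 2371 lower, and DESeq2 1.42.0 called 993 higher and 1181 lower; all genes called by DESeq2 were also called, in the same direction, by limma and by edgeR.

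The test was checked on simulated data drawn from the means and dispersions of the 13661 genes, in 5 runs with 200 changed genes each. It called 50.2% of 249 genes changed 1.25-fold, 78.7% of 249 changed 1.5-fold, 86.8% of 250 changed 2-fold and 97.2% of 249 changed 4-fold. The dispersions were estimated from these same 4 libraries, so the simulated rates hold only for their spread, which may be technical. Of all calls in these runs 10.5% were unchanged genes, above the nominal 5%, and 42.3% of these false calls were among the 1% of genes with the highest dispersion; the false share was 10.9% with edgeR. When the genes called here were simulated as changed by their fitted amounts, the false share of the limma calls was 3.26%. This second simulation takes every call as true, so it cannot show how many of the calls made here are false. Camera called the shifted list in 5 of 5 runs, with simulated genes that varied independently, which says nothing about correlated lists.

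The groups, tests, 32 gene lists and all alternatives except those named as added were fixed before the data were examined. Named genes followed a fixed rule: EMP2; the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM, with both knockdown libraries on the same side of both controls and a symbol that is not a pseudogene or an unnamed locus; and up to 4 called members of each list by smallest adjusted p, or the 2 most abundant where none was called. Some genes that this rule names are not reported here. Long intergenic transcripts with LINC numbers and open reading frames named by chromosome were taken as unnamed loci, a reading made after values had been seen. Other genes named were chosen after their values were seen; in the accounts of the lists these are marked as further members or complete a small count. Positions come from GENCODE release 29 on GRCh38, which held 97.0% of the genes tested, with older symbols matched through RefSeq synonyms. For 28 genes the symbol had been turned into a date, and these genes were known by their titles. Among the genes tested, 46 had values identical to those of another gene in all libraries, and 32 were at 0 in 1 library and at 1 CPM or more in the other of the same group. Genes with near-identical copies are uncertain, since the treatment of shared reads is not known; among those named, this holds for RGPD8, AKR1C2, ALPP, the MTRNR2L genes, the HLA genes and the histone genes.

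The alternatives were pseudocounts of 0.1 and 1, no filter on low values, a mean of at least 5 CPM, scaling by size factors, by sums or by quantiles, limma without the trend, edgeR, DESeq2, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were keeping 1 gene of each identical set, leaving out the genes at 0 in 1 library alone, and a robust empirical Bayes step. Words of 7 bases in 3' UTRs were tested with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.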

Results

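Gene expression was compared between SUM149PT breast cancer cells that stably carried an shRNA against EMP2 and cells that carried a control vector, with 2 libraries in each group. EMP2 encodes epithelial membrane protein 2, a small membrane protein of the PMP22 family, and the title of the series places it among the targets on breast cancer stem cells. The libraries held between 13360907 and 14647053 recovered reads, with 17515 to 17633 genes above 0 in each. The 10 most abundant genes took 4.68% to 4.86% of the CPM of a library.

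EMP2 mRNA was lower in both knockdown libraries. It stood at 126.1 and 124.6 CPM in the control libraries and at 23.0 and 22.6 CPM in the knockdown libraries, so that the knockdown mean of 22.8 ± 0.288 CPM (SD, n = 2) was 18.2% of the control mean of 125.3 ± 1.08 CPM (SD, n = 2). The log2 change was -2.43 (SE 0.051, 95% confidence interval -2.54 to -2.32, limma adjusted p = 3.7e-15). The gene lies on the minus strand of chromosome 16 from 10528422 to 10580698 (GRCh38). Of the EMP2 relatives EMP1, EMP3 and PMP22, EMP1 rose by a small amount, from 244.9 ± 4.27 to 280.1 ± 0.21 CPM (SD, n = 2; log2 change 0.19). EMP3 was at a log2 change of -0.16 and PMP22 at -0.08, neither past the test, and the count was also 1 adjusted over the list alone. The median (-0.083) and mean (-0.016) of these 3 genes were below 0 while camera placed them, without a call, on the higher side (adjusted p = 0.738).

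**Figure D1:**
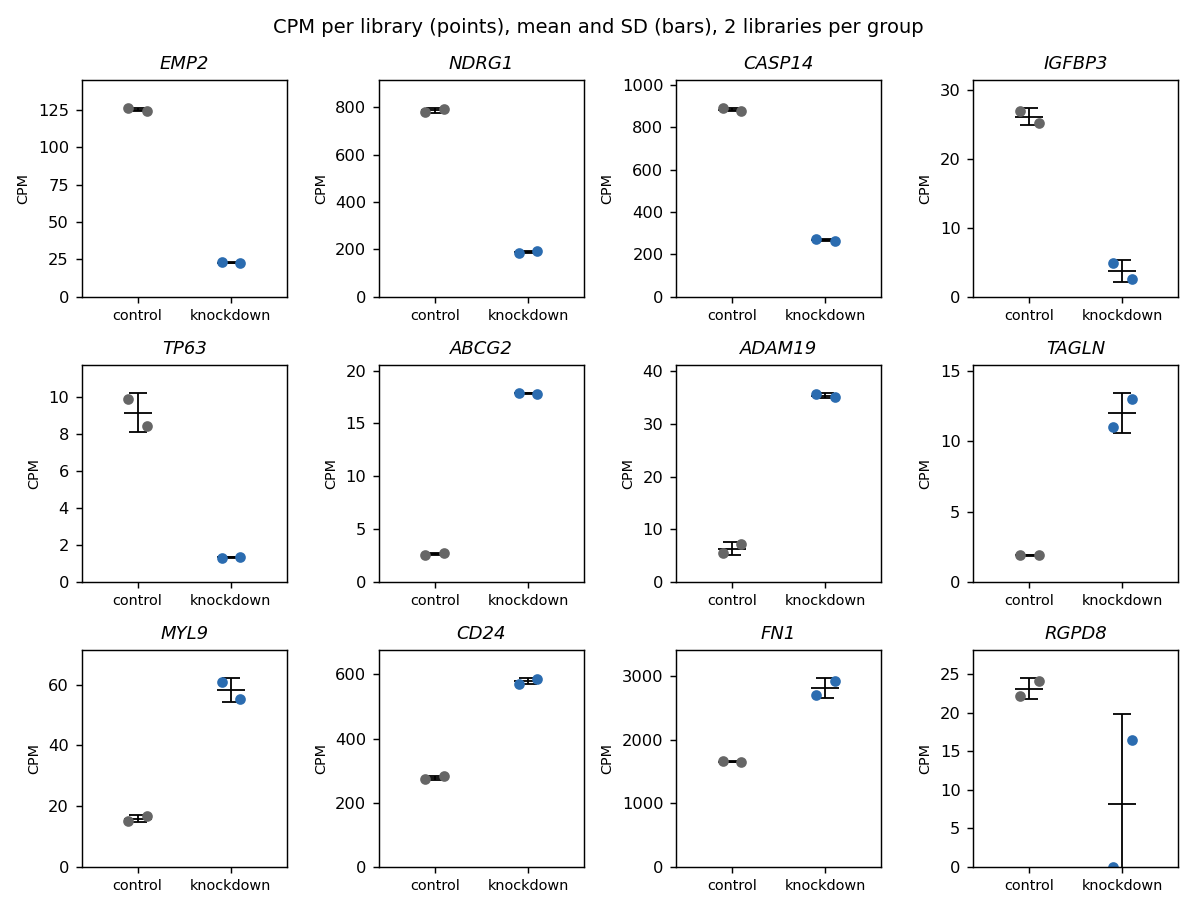
CPM of 12 named genes (one panel each, vertical axis CPM from 0) in the control and knockdown groups. Points are the 2 libraries of each group and bars the mean and SD; the bar of RGPD8 is clipped at 0. EMP2 stands at 126.1 and 124.6 CPM in the controls and 23.0 and 22.6 CPM in the knockdowns, and RGPD8 at 0 and 16.4 CPM in the knockdowns.

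Knockdown cells had more mRNA of the drug efflux transporter ABCG2, the actin-binding protein TAGLN and the myosin light chain MYL9, and less of NDRG1, the epidermal protease CASP14, the growth factor binding protein IGFBP3 and the basal transcription factor TP63. ABCG2 rose 6.75-fold in mean CPM, from 2.64 ± 0.118 to 17.8 ± 0.0254 CPM (SD, n = 2; log2 change 2.55, SE 0.14, limma adjusted p = 3.24e-10). NDRG1, a gene known to be induced by low oxygen and differentiation, fell from 786.3 ± 10.4 to 188.4 ± 4.61 CPM (SD, n = 2; log2 change -2.06, SE 0.028, limma adjusted p = 1.01e-17). CASP14 fell from 883.3 ± 7.81 to 266.7 ± 4.92 CPM (SD, n = 2; log2 change -1.73, SE 0.026, limma adjusted p = 2.39e-17). In all, 2269 genes were higher and 2294 lower in the knockdown (limma, adjusted p under 0.05), 33.4% of the 13661 genes tested. Most of these changes were small: 1873 of the higher and 1894 of the lower genes changed by under 1.5-fold, and 119 rose and 119 fell by at least 2-fold. The counts depended on the test, with 993 higher and 1181 lower by DESeq2 and 916 higher and 1016 lower by limma without the abundance trend. They also rest on a small spread between libraries of a group, an edgeR coefficient of variation of 2.15% beyond counting noise. This spread may be technical, so the counts and p-values do not show how many genes would differ between independent cultures. At 2-fold 59 were higher and 72 lower among genes with a mean of at least 5 CPM. The 2-fold counts also moved with the pseudocount, to 162 higher and 147 lower at 0.1 and to 86 and 90 at 1. With edgeR they were 167 and 149.

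Among the genes with the largest rises was ADAM19, a membrane metalloprotease, which rose from 6.29 ± 1.17 to 35.4 ± 0.475 CPM (SD, n = 2; log2 change 2.41). TAGLN rose by 2.39 on the log2 scale (SE 0.16). MYL9 rose from 15.8 ± 1.16 to 58.1 ± 3.98 CPM (SD, n = 2). SCEL, a protein of the cornified envelope, rose by 2.15 on the log2 scale, LDB3, a protein of the muscle Z-disc, by 1.83, and CCDC80, a matrix protein, by 1.67. The sulfatase ARSI rose from 5.19 ± 0.588 to 15.6 ± 1.51 CPM (SD, n = 2). The cytolinker EPPK1 (1.47), the complement regulator CFI (1.41), the urokinase gene PLAU (1.38) and the cytokine gene TNFSF15 (1.38) completed the 12, with log2 changes in brackets. Their limma adjusted p values lay between 4.4e-12 for CCDC80 and 3.22e-06 for TNFSF15. ABCG2 lies on chromosome 4 from 88090264 to 88231322 and ADAM19 on chromosome 5 from 157395534 to 157575775 (GRCh38).

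Among the falls, IGFBP3 fell by 2.70 on the log2 scale (SE 0.18). TP63, the p63 transcription factor of basal epithelium, fell from 9.15 ± 1.05 to 1.32 ± 0.0403 CPM (SD, n = 2; log2 change -2.40). The interferon-induced gene IFI6 fell by 2.16, the carboxylesterase CES1 by 1.90, TNFAIP6, a hyaluronan-binding protein, by 1.77 and the aldo-keto reductase AKR1C2 by 1.73 on the log2 scale. The carbonic anhydrase CA12 fell by 1.69 and the transcription factor SP8 by 1.68. Limma adjusted p values of these genes lay between 1.39e-10 for IFI6 and 1.51e-07 for TNFAIP6. RGPD8, one of a family of near-identical genes, had the lowest log2 change of the 12 (-3.02, limma adjusted p = 0.0159), but its size rests on 1 library: it stood at 22.2 and 24.1 CPM in the controls and at 0 and 16.4 CPM in the knockdowns. Without knockdown replicate 1 its log2 change was -0.48 and without knockdown replicate 2 it was -5.56, a value set by the pseudocount. Its call was lost with edgeR (adjusted p = 0.0554) and DESeq2 (adjusted p = 0.851), and over its alternatives the adjusted p ran from 1.37e-31 to 0.851. NDRG1 lies on chromosome 8 from 133237171 to 133302022, IGFBP3 on chromosome 7 from 45912245 to 45921874 and TP63 on chromosome 3 from 189631416 to 189897279 (GRCh38).

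**Figure D2:**
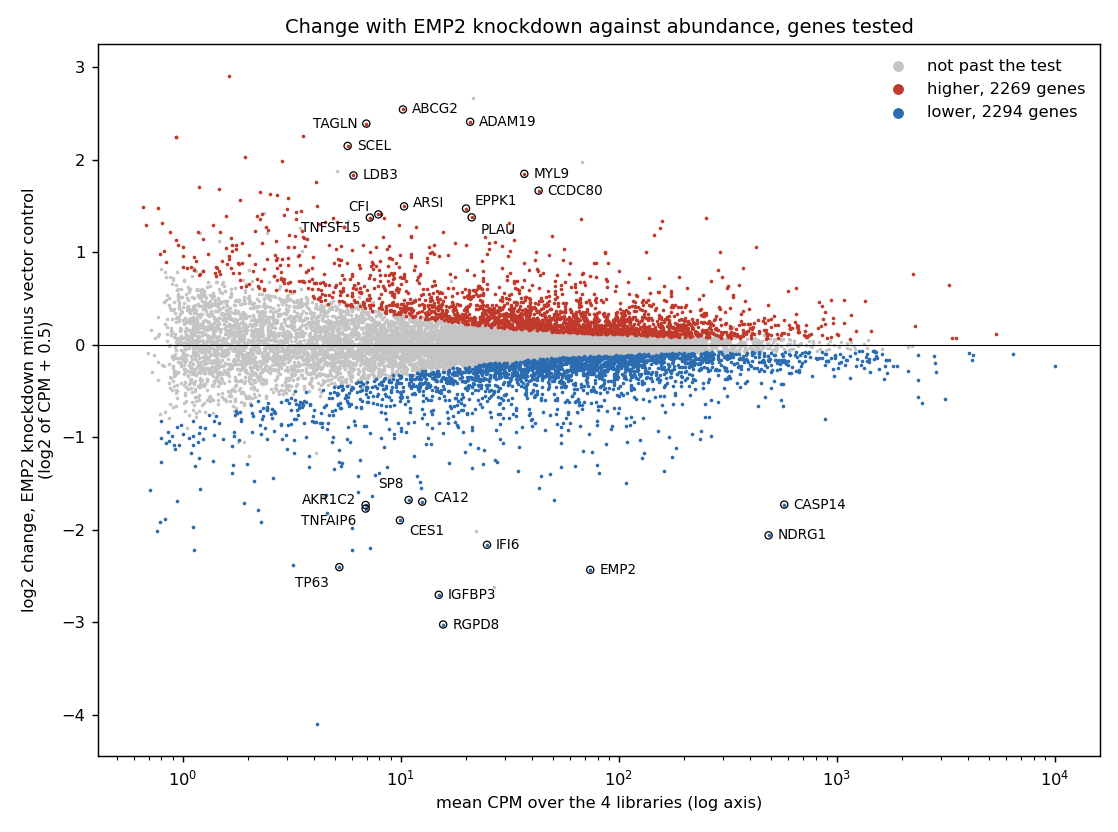
Log2 change (knockdown minus control, vertical) against mean CPM over the 4 libraries (horizontal, log axis) for the 13661 genes tested. Each point is a gene, red for the 2269 called higher, blue for the 2294 called lower and grey for the rest; circles mark the named genes, which were drawn from those with a mean of at least 5 CPM.

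Of 30 gene lists tested against the other genes, 9 were higher and 4 lower in the knockdown by camera with its preset correlation. With a correlation estimated from the data camera called 0 lists, 2 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.332, while fry called 11 higher and 7 lower. For each of the 13 lists called, the p with an estimated correlation was the highest of all alternatives run. That test has 2 degrees of freedom, and lists with an estimated correlation below the preset 0.01 lost their calls too. Among them were cholesterol synthesis (-0.000235) and MHC class I antigen presentation (-0.0463), both at a camera adjusted p = 0.332. The loss is thus no measure of correlation within a list, nor does it show the lists to be free of it. Of the genes that the fixed rule names, limma without the trend ended the calls of 19: RGPD8, EMP1, ALDH3A2, KRT7, TOP2A, MCM2, AURKA, NOTCH2, SFRP1, WNT5A, GLI1, CAV2, TNFRSF10B, CDKN1A, GADD45A, HIST1H2BD, NEAT1, SNHG1 and NEFL.

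Breast cancer stem cell markers moved in both directions. Of 14 tested, 3 rose and 7 fell, and the numbers adjusted over the list alone were 3 and 7. Besides ABCG2, the integrin chain ITGB1 rose from 586.7 ± 1.53 to 698.2 ± 1.51 CPM (SD, n = 2). The integrin chain ITGA6 fell from 144.2 ± 4.27 to 84.1 ± 1.27 CPM (SD, n = 2; log2 change -0.77) and the transcriptional regulator ID1 fell by 0.36 on the log2 scale. Further members that fell were CD44 (-0.23) and MYC (-0.36), and ALDH1A3 rose by 0.61. The list was not called (camera adjusted p = 0.109). Its median was -0.27 and its mean 0.016, with the test on the lower side. Among the aldehyde dehydrogenases, enzymes whose activity is used to sort stem-like cells, 2 of 15 rose and 7 fell (2 and 7 adjusted over the list alone). ALDH2 fell from 80.5 ± 1.76 to 48.5 ± 2.87 CPM (SD, n = 2), ALDH3B1 by 0.28 and ALDH3A2 by 0.26 on the log2 scale, and ALDH1A3 rose; this list too was not called (camera adjusted p = 0.109). Drug efflux transporters went both ways, with 3 of 10 rising and 4 falling (3 and 5 adjusted over the list alone): besides ABCG2, ABCC5 rose by 0.55, and ABCC3 fell by 0.40 and ABCC1 by 0.27. Their median was -0.27, their mean 0.16 and the test on the lower side (camera adjusted p = 0.579).

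Genes induced by low oxygen were lower in the knockdown. Of 28 tested, 19 fell and 2 rose (19 and 2 adjusted over the list alone). Their median was -0.18, and -0.10 with quantile scaling. Camera gave an adjusted p = 1.69e-08 and an adjusted p = 0.332 with an estimated correlation. Besides NDRG1, the hexokinase HK2 fell from 86.5 ± 3.28 to 46.7 ± 1.68 CPM and the carbonic anhydrase CA9 from 56.1 ± 0.625 to 33.8 ± 0.981 CPM (SD, n = 2), and the stress-response gene DDIT4 fell by 0.25 on the log2 scale. Angiogenic factors were split, with 4 of 18 rising and 5 falling (4 and 5 adjusted over the list alone). ANGPT1, a ligand of the endothelial receptor TIE2, fell from 117.3 ± 1.37 to 44.7 ± 2.37 CPM and VEGFA from 69.7 ± 5.84 to 46.0 ± 0.574 CPM (SD, n = 2), whereas CYR61 rose by 1.32 and PDGFB by 1.37 on the log2 scale. This list was not called (camera adjusted p = 0.699), with a median of 0.0046 and a mean of 0.045 but the test on the lower side; VEGFA and ANGPTL4 are in both lists.

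Mesenchymal genes were higher as a list, and so were genes of epithelial junctions. Of 21 mesenchymal genes 11 rose and 5 fell (11 and 5 adjusted over the list alone); camera gave an adjusted p = 0.00181 and an adjusted p = 0.332 with an estimated correlation. Fibronectin (FN1) rose from 1655 ± 9.87 to 2814 ± 154.3 CPM, the matrix protein TGFBI from 268.1 ± 1.10 to 478.0 ± 15.2 CPM and the collagen chain COL5A1 from 36.7 ± 3.16 to 75.5 ± 0.391 CPM (SD, n = 2). The collagen cross-linking enzyme LOX fell by 0.85 on the log2 scale, and so did a further member, the intermediate filament vimentin (VIM), by 0.41. Beside these, the fibroblast markers moved apart: FAP rose by 1.10, DCN fell by 0.79 and COL1A1 was at 0.14 without passing the test, so that 1 of 3 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.738). Of 27 epithelial junction genes 17 rose and 2 fell (17 and 2 adjusted over the list alone); camera gave an adjusted p = 9.17e-06 and an adjusted p = 0.332 with an estimated correlation. E-cadherin (CDH1) rose from 343.3 ± 4.07 to 449.2 ± 7.28 CPM, and the tight junction gene CLDN4 from 43.7 ± 2.18 to 74.5 ± 1.20 CPM (SD, n = 2). P-cadherin (CDH3) rose by 0.47 and the scaffold gene TJP1 by 0.50 on the log2 scale.

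Integrins and focal adhesion genes were higher, with 13 of 26 rising and 5 falling (14 and 5 adjusted over the list alone); camera gave an adjusted p = 0.0354 and an adjusted p = 0.332 with an estimated correlation. The integrin chains ITGAV and ITGA5 rose by 0.62 and 0.57 on the log2 scale, and ITGA6 and the integrin activator FERMT2 fell by 0.77 and 0.56. Matrix metalloproteinases and their inhibitors were higher as a list, with 9 of 21 rising and 2 falling (10 and 2 adjusted over the list alone); camera gave an adjusted p = 0.0146 and an adjusted p = 0.332 with an estimated correlation. TIMP2 rose from 58.8 ± 0.436 to 97.9 ± 3.82 CPM while TIMP1 fell from 313.3 ± 4.04 to 182.4 ± 7.28 CPM (SD, n = 2); both are inhibitors of metalloproteinases. The membrane protease ADAM9 rose by 0.41 and the plasminogen activator PLAT by 0.68. Among genes with a mean of at least 5 CPM the calls of the integrin list (camera adjusted p = 0.0556) and of the metalloproteinase list (camera adjusted p = 0.0762) were lost.

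Lineage markers of the mammary epithelium also changed. Of 14 luminal genes 8 rose and 3 fell (9 and 3 adjusted over the list alone); camera gave an adjusted p = 0.032, an adjusted p = 0.332 with an estimated correlation, and an adjusted p = 0.0802 among genes with a mean of at least 5 CPM. CD24, a surface protein that is low on cells sorted as breast cancer stem cells, rose from 278.1 ± 6.34 to 578.2 ± 9.67 CPM (SD, n = 2; log2 change 1.05, limma adjusted p = 6.06e-14). The keratins KRT8 and KRT7 rose by 0.23 and 0.21, whereas the luminal transcription factor GATA3 fell from 136.4 ± 4.46 to 79.0 ± 1.27 CPM (SD, n = 2). Of 19 basal and myoepithelial genes 6 rose and 10 fell (6 and 10 adjusted over the list alone), and the list was not called (camera adjusted p = 0.16). The laminin chain LAMA3 rose by 0.73 on the log2 scale, and EGFR fell from 215.7 ± 7.36 to 138.8 ± 0.504 CPM and KRT15 from 73.8 ± 3.39 to 35.3 ± 2.86 CPM (SD, n = 2).

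**Figure D3:**
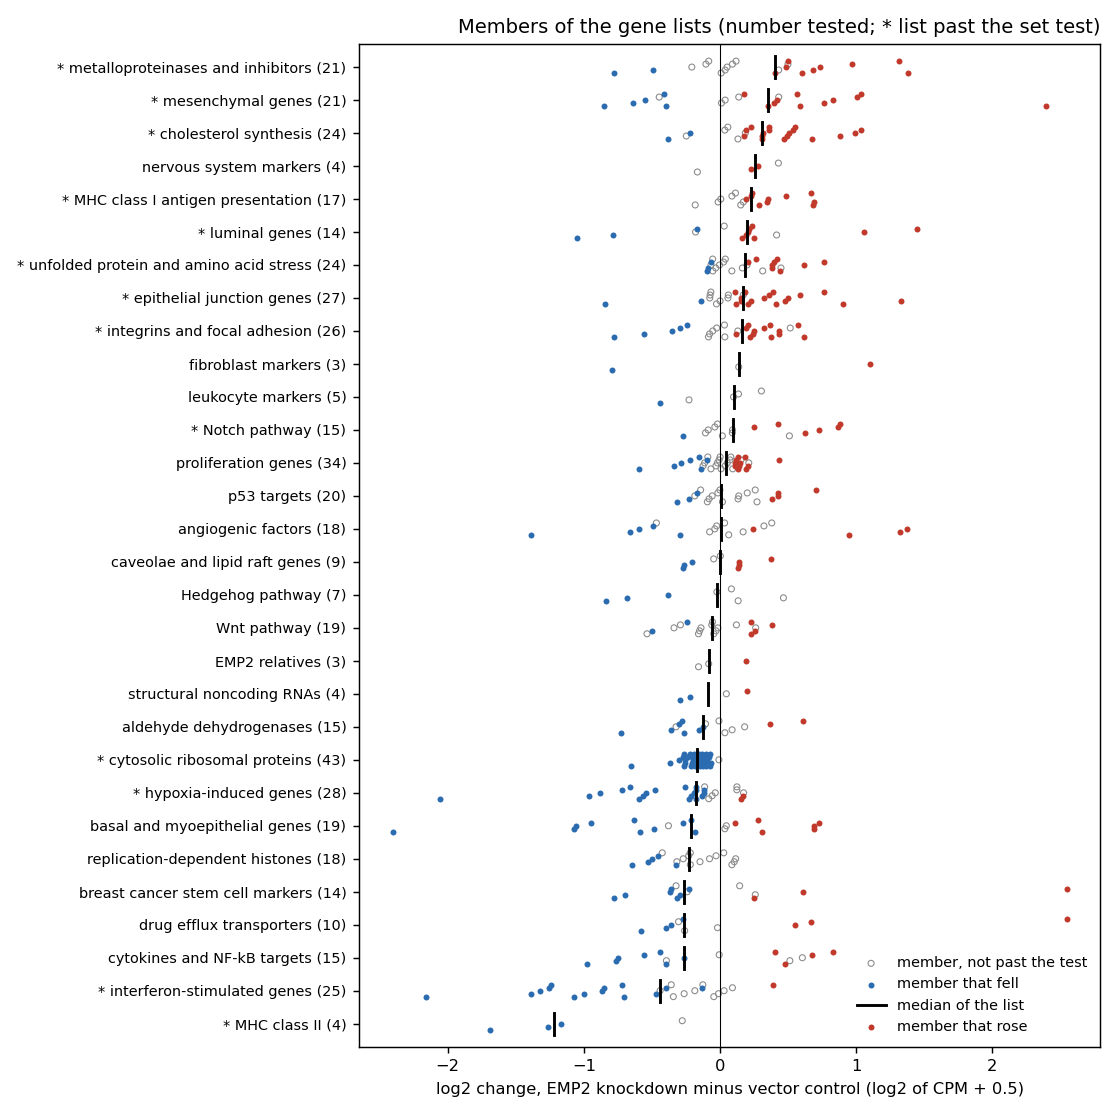
Log2 change (knockdown minus control, horizontal) of each tested member of the 30 gene lists, with lists ordered by their median and the number tested in brackets. Red points are members that rose, blue points members that fell, open points those not past the test and black bars medians; an asterisk marks the 9 lists called higher and 4 called lower by camera with its preset correlation, of which 0 were called with an estimated one.

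Interferon-stimulated genes were lower, while genes of MHC class I antigen presentation were higher. Of 25 interferon-stimulated genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.44; camera gave an adjusted p = 1.66e-06 and an adjusted p = 0.332 with an estimated correlation. IFI44L fell from 78.2 ± 4.28 to 31.0 ± 1.05 CPM, IFI27 from 28.2 ± 0.422 to 13.2 ± 2.06 CPM and BST2 from 220.1 ± 0.227 to 166.8 ± 4.34 CPM (SD, n = 2); the member that rose was SAMD9 (0.39). Of 17 MHC class I genes 10 rose (11 adjusted over the list alone) and the others did not pass; camera gave an adjusted p = 5.57e-06 and an adjusted p = 0.332 with an estimated correlation. Calreticulin (CALR), a chaperone of peptide loading, rose from 897.6 ± 9.87 to 1259 ± 17.1 CPM (SD, n = 2), its partner PDIA3 by 0.23, the peptide-trimming enzyme ERAP2 by 0.69 and the peptide transporter TAP1 by 0.69 on the log2 scale; CALR and PDIA3 are also general chaperones of the endoplasmic reticulum. A further member, B2M, the light chain of class I, was at 288.4 ± 11.6 and 289.5 ± 0.647 CPM (SD, n = 2).

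MHC class II genes were low, with no mean above 5 CPM, and 3 of the 4 tested fell (3 adjusted over the list alone); camera gave an adjusted p = 0.0354 and an adjusted p = 0.332 with an estimated correlation. The class II transactivator CIITA went from 4.69 ± 0.760 to 1.80 ± 0.00298 CPM, CD74 from 1.70 ± 0.0577 to 0.183 ± 0.0463 CPM and HLA-DMB from 1.33 ± 0.273 to 0.257 ± 0.0597 CPM (SD, n = 2). In the knockdown CD74 and HLA-DMB lay close to the value of 3 reads, 0.208 to 0.227 CPM, so the size of their falls is uncertain. Both passed the filter of 1 CPM through the control libraries alone, and DESeq2 gave neither an adjusted p. The list's call was lost without control replicate 1 (adjusted p = 0.0853), without control replicate 2 (0.0565) and without knockdown replicate 2 (0.0983), by camera. That of HLA-DMB was lost without control replicate 1 (limma adjusted p = 0.0562, the highest of its alternatives, from 0.00232). The leukocyte marker CD68 fell beside them, by 0.44 on the log2 scale, as 1 of 5 leukocyte markers tested (1 adjusted over the list alone); that list had a median of 0.099, a mean of -0.026 and a test on the lower side without a call (camera adjusted p = 0.621). Inflammatory cytokines and NF-kB targets were split, with 4 of 15 rising and 7 falling (6 and 7 adjusted over the list alone; camera adjusted p = 0.579). The inhibitor NFKBIA fell by 0.39, the superoxide dismutase SOD2 by 0.44 and the chemokine CXCL1 by 0.75, and the apoptosis inhibitor BIRC3 rose by 0.83.

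Most genes of cholesterol synthesis rose. Of 24 tested, 17 rose and 2 fell (17 and 3 adjusted over the list alone), with a median of 0.31; camera gave an adjusted p = 2.25e-07 and an adjusted p = 0.332 with an estimated correlation. MSMO1 rose by 0.99 on the log2 scale. SQLE, the squalene epoxidase, rose from 54.0 ± 0.901 to 100.2 ± 6.74 CPM and IDI1 from 53.5 ± 1.49 to 85.7 ± 0.439 CPM (SD, n = 2). In the list of unfolded protein and amino acid stress 9 of 24 rose and 3 fell (10 and 4 adjusted over the list alone); camera gave an adjusted p = 0.0134 and an adjusted p = 0.332 with an estimated correlation. The 4 members with the smallest adjusted p were chaperones or helpers of folding in the endoplasmic reticulum. HSP90B1 rose from 735.3 ± 7.21 to 981.0 ± 11.1 CPM (SD, n = 2), and HSPA5 rose by 0.62, PDIA4 by 0.38 and DNAJB9 by 0.77 on the log2 scale. A further member, ATF4, the transcription factor of the amino acid response, fell by 0.09. Of 20 p53 targets 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.621). AEN rose by 0.43, the cell cycle inhibitor CDKN1A by 0.43 and GADD45A by 0.71, and TNFRSF10B fell by 0.22. Without knockdown replicate 1 GADD45A was at 0.44 and no longer called (limma adjusted p = 0.134, against 0.000177 to 0.134 over its alternatives). Neither CDKN1A (DESeq2 adjusted p = 0.0882, against 0.000777 to 0.0882) nor GADD45A (0.0701) was called by DESeq2.

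Of the developmental pathways, Notch genes were higher. Of 15 tested, 6 rose and 1 fell (6 and 1 adjusted over the list alone); camera gave an adjusted p = 0.0135 and an adjusted p = 0.344 with an estimated correlation. The receptor NOTCH3 rose from 103.7 ± 0.191 to 172.2 ± 17.9 CPM, NOTCH1 from 25.7 ± 4.30 to 47.6 ± 3.78 CPM and the ligand JAG1 from 47.3 ± 0.453 to 73.1 ± 1.29 CPM (SD, n = 2), and NOTCH2 by 0.25 on the log2 scale. Wnt genes were not called as a list (camera adjusted p = 0.738): 4 of 19 rose and 2 fell (4 and 2 adjusted over the list alone), with CTNNB1 (0.23) and WNT5A (0.38) higher and SFRP1 (-0.24) and FZD1 (-0.50) lower. Among the 7 Hedgehog genes tested 3 fell (3 adjusted over the list alone; camera adjusted p = 0.409), namely GAS1 (-0.84), CDON (-0.38) and GLI1 (-0.68). DESeq2 did not call CDON (adjusted p = 0.0641, against 0.000461 to 0.0641 over its alternatives) or GLI1 (0.0949, against 0.000672 to 0.0949). Without knockdown replicate 2 the limma call of GLI1 was lost too (adjusted p = 0.0522). Genes of caveolae and lipid rafts were split, with 4 of 9 rising and 3 falling (4 and 3 adjusted over the list alone; camera adjusted p = 0.768). The caveolins CAV1 and CAV2 fell by 0.27 and 0.21 and FLOT2 by 0.26, and PRKCDBP rose by 0.38 on the log2 scale. Their median of 0.0025 and mean of 0.00041 were above 0 while the test was on the lower side, and the median was below 0 with scaling by size factors.

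Proliferation genes were not called as a list: 11 of 34 rose and 7 fell (12 and 7 adjusted over the list alone; camera adjusted p = 0.579). The survivin gene BIRC5 fell from 103.0 ± 2.77 to 68.1 ± 0.162 CPM (SD, n = 2), the topoisomerase TOP2A by 0.22 and the replication factor MCM2 by 0.34, whereas the mitotic kinase AURKA rose by 0.19. Of 18 replication-dependent histone genes 5 fell (5 adjusted over the list alone) and the others did not pass; HIST1H2BK fell by 0.45, HIST1H2AC by 0.53, HIST1H2BD by 0.32 and HIST1H1C by 0.50 on the log2 scale, and the list was not called (camera adjusted p = 0.0647). DESeq2 did not call HIST1H1C (adjusted p = 0.0888, against 0.001 to 0.0888 over its alternatives).

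Cytosolic ribosomal protein mRNAs were lower, by amounts that differed between genes. Of 43 tested, 42 fell (42 adjusted over the list alone) and RPS2 did not pass. The median was -0.17, with changes between -0.66 and -0.0079. Camera gave an adjusted p = 2.81e-21 and an adjusted p = 0.332 with an estimated correlation. That correlation came to 0.49 in this list, but lists with estimates below the preset 0.01 had the same adjusted p. RPS20 fell from 533.6 ± 22.5 to 338.5 ± 5.53 CPM and RPL4 from 1865 ± 25.8 to 1444 ± 20.9 CPM (SD, n = 2), and RPL13A fell by 0.30 on the log2 scale. Noncoding RNAs listed as signs of RNA quality and depletion moved beside them: the snoRNA host genes GAS5 and SNHG1 fell by 0.30 and 0.22 and the nuclear RNA NEAT1 rose by 0.20, so that 1 of 4 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.689). NEAT1 was at 0.12 without control replicate 1, and SNHG1 was not called by DESeq2 (adjusted p = 0.0675, against 0.000698 to 0.0675 over its alternatives). The mitochondrially encoded mRNAs were not analysed here.

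Of 4 nervous system markers 2 rose (2 adjusted over the list alone; camera adjusted p = 0.109): TUBB3 from 140.5 ± 0.809 to 171.0 ± 4.32 CPM (SD, n = 2) and NEFL by 0.23 on the log2 scale. NEFL was not called by DESeq2 (adjusted p = 0.143, against 0.00259 to 0.143 over its alternatives), nor by limma without control replicate 1 (adjusted p = 0.0659) or without knockdown replicate 2 (0.0558). The endothelial markers ENG and PECAM1, the 2 of their list above the filter, were at log2 changes of -0.04 and -0.50 and did not pass the test (limma adjusted p = 0.573 and 0.119).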

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

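Of single genes, only EMP2 and the 127 others that the fixed rule names were followed through the alternatives. None of these and no called list changed direction where it was refitted. The robust step, the sets of identical genes kept once and the omission of genes at 0 in 1 library alone were chosen after seeing the data. The last 2 were run for the counts of calls alone. EMP2 remained called in the 16 alternatives that refitted it, with a log2 change of -2.42 to -2.44 when each library was left out in turn. DESeq2 called 993 genes higher and 1181 lower, and limma without the trend 916 and 1016, against 2269 and 2294; the cause was not tested. With a mean of at least 5 CPM 59 genes were at least 2-fold higher and 72 lower, since fewer low genes were tested. Camera with an estimated correlation, on 2 degrees of freedom, called 0 lists higher and 0 lower. Fry, which does not compare a list with other genes, called 11 and 7. Other settings kept the counts of calls within 1.5 times, from 1823 to 2616 higher and from 1842 to 2416 lower; scaling by sums gave 2616 higher and 1993 lower, and the robust step 2400 and 2416. Leaving out 1 library gave 1823 to 2029 higher and 1842 to 2059 lower, with the lone library of a group assumed to vary like the others.

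The labels number the libraries of both groups 1 and 2 but do not say that equal numbers pair them, and deviations of equally numbered libraries did not correlate across genes (-0.003). A replicate block gave 2162 higher and 2180 lower, and ended no call of these genes or of a list.

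Of the 127 genes besides EMP2, 22 lost their call in at least 1 alternative, 19 of them in limma without the trend and 8 in DESeq2, and PECAM1 gained one without the trend (adjusted p = 0.0284). RGPD8 also lost its call with no filter, quantile scaling and the robust step (adjusted p = 0.488). Depth limits the genes near 1 CPM, where 3 reads come to 0.208 to 0.227 CPM.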

Other observations

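The genes and groups in this part were picked after their values were seen, as were the fibroblast test and the test of the passenger strand; the lists of SRF targets, YAP targets and mRNAs with a 5' terminal oligopyrimidine tract were also written then, and are tested on the members whose values had not been looked at when the lists were written.

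Among single genes, mRNA of the protease inhibitor SERPINE2 fell from 160.3 to 56.6 CPM, stanniocalcin STC1 from 180.4 to 80.3 CPM, the proteoglycan BGN from 64.3 to 21.7 CPM and the growth factor EREG from 118.3 to 55.8 CPM (means, n = 2). The differentiation keratin KRT10 fell by 1.14 on the log2 scale. The transglutaminase TGM2 rose from 90.8 to 218.4 CPM, the coagulation factor gene F3 from 88.3 to 179.1 CPM and the placental alkaline phosphatase ALPP, whose paralogs share much of its sequence, from 139.8 to 361.7 CPM. The estrogen receptor gene ESR1 rose from 1.65 to 5.32 CPM. SUMF2 fell by 1.36, FBXO9 by 1.39 and MRPL53 by 1.33 on the log2 scale. The hypoxia-inducible factor genes HIF1A and EPAS1 fell by 0.18 and 0.47. Limma adjusted p values of the genes named so far lay between 7.41e-15 for ALPP and 3.41e-05 for ESR1. Of the MTRNR2L genes, nuclear copies of a mitochondrial ribosomal RNA, MTRNR2L2 fell from 3761 to 2504 CPM and MTRNR2L8 from 2808 to 1897 CPM. Together these genes took 0.807% and 0.815% of the CPM in the control libraries and 0.548% and 0.552% in the knockdown libraries. Since the treatment of shared reads is not known, reads of the mitochondrial ribosomal RNA itself may be counted here. The fall may thus lie in its level or its depletion rather than in the nuclear genes, which was not tested.

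Actin cytoskeleton genes rose beyond the named TAGLN and MYL9: of 29 SRF targets and actin genes tested 25 rose and 1 fell, among them FLNA (0.65), TPM1 (1.18) and PALLD (1.19). The fibroblast marker FAP rose too (1.10), but a carry-over of fibroblasts is argued against, since the abundant fibroblast mRNAs COL1A1 and DCN had a median log2 change of -0.328, COL1A2 was at 0 in all 4 libraries and COL3A1 reached at most 0.227 CPM. The members not seen before had a median of 0.367 for SRF targets (14 of 17 rose) and 0.284 for YAP targets (11 of 16 rose and DOCK5 fell by 0.69), and of 10000 random lists of like abundance a share of 1e-04, the smallest these can give, lay as high. Of all 22 YAP targets tested 16 rose and 2 fell, IGFBP3 (-2.70) and DOCK5, so a shared activity of SRF or YAP, which share targets and are not separated by these data, is a candidate explanation for most but not all of these genes. Whether it follows from the loss of EMP2 or from a difference between the infected cell lines stays open and was not tested.

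A scaling factor per library moves all genes alike and cannot set ribosomal protein mRNAs apart from the rest. Quantile scaling, which treats levels differently, moved the gap of their median to that of all genes from -0.169 to -0.122, which argues against scaling as the whole cause of their fall. A bias of short, abundant transcripts cannot be told apart from it: other genes matched on length and abundance had a median of -0.0561, and 0.895 of 10000 matched sets lay closer to 0 than the midpoint between 0 and the list's median of -0.165, short of the 95% set before. Other mRNAs with a 5' terminal oligopyrimidine tract, such as translation factors, fell too. Their unseen members had a median of -0.119 and 17 of 21 fell (share of random lists of like abundance as low 0.0061). These random lists were not matched on length, so a bias of short transcripts stays open here too. As a hypothesis, the falls of these mRNAs and of ribosomal protein mRNAs could be a change of the whole class. EMP2 itself and other differences between the infected lines stay open as its origin and were not tested.

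The shRNA may have lowered other genes through its seed, the bases that pair with 3' UTRs. Over 12346 genes no word of 7 bases found in an EMP2 transcript passed the limit of 4.496 on the low side (lowest z -3.872). The test found a fall of 0.1 on the log2 scale in 19 of 20 trials, planted evenly in all genes with a word. The most common words were not used in these trials. This argues against a guide seed that lowered its genes by a mean of 0.1 or more. Smaller mean falls were not planted, so a weaker seed effect and effects on single genes stay open. So do 159 words too rare or too common to test. The lowest word of all, AGTGCAA, passed the limit of 4.496 (z -5.062) in 1658 genes, with a difference of -0.046 on the log2 scale. Its reverse complement TTGCACT lies in an EMP2 transcript, as for 39.86% of words, so a seed of the passenger strand cannot be told apart from chance or from a cellular microRNA. The sequence of the construct is not used here.

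Among the 8 called genes at 0 in 1 library and at 1 CPM or more in the other of its group were RGPD8 and the read-through genes RPL17-C18orf32 and RAB4B-EGLN2; the last stood at 0 and 9.14 CPM in the knockdown libraries.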
